A study of Homo sapiens with 32 samples.

How the data were processed

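Left ventricular tissue taken away from infarcted areas was sequenced from 15 control hearts and 15 hearts with ischemic cardiomyopathy (ICM, heart failure that follows narrowed coronary arteries). Per the labels' protocols, tissue was frozen within hours of explantation, RNA was extracted with Trizol and columns, ribosomal RNA was depleted, and each heart gave 1 Illumina library. Per the same labels, RNA of the 15 hearts of each group was also pooled and sequenced on a SOLiD instrument with a strand-specific kit, which gave 2 pooled libraries.

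The deposited table holds FPKM (fragments scaled by transcript length and library size) for 27903 RefSeq transcript rows of 16028 gene symbols, and, per the submitters' processing notes, TopHat 1.2.0, Cufflinks and edgeR were used with the genome builds hg19 and GRCh37. The role of each tool and the FPKM denominator are not given in the sources used here. The authors also deposited a log2 fold change of ICM over control, a log2 concentration, a p-value and an adjusted p-value per transcript, which per the file headers belong to their own comparison. These columns are set beside the values computed here only where the authors' deposited table is named. The gene table of assembly GRCh38 was used for names alone, and no coordinates are printed because the builds differ. It matched 26859 of 27854 transcript identifiers.

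From the deposited table, 49 identical repeat rows were removed. A spreadsheet had turned 19 symbols on 48 rows into dates, and 46 of these rows were given their symbols back through the transcript identifier. XIST, TSIX and Y-linked genes, 17 symbols in all, were left out. That left 27825 transcripts of 16013 genes, of which 6021 genes had more than 1 transcript. FPKM was summed over the transcripts of a symbol. Transcripts of a gene moved together across libraries with a median correlation of 0.9986 over 1363 genes, so a sum may count shared fragments repeatedly. The correlation alone does not show whether it does, and this was not checked. Summed levels of genes with several transcripts may therefore be too high, while a ratio between groups would be little affected. The highest transcript per gene was used as an alternative.

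Each library was divided by its median-of-ratios factor, which ran from 0.603 to 1.71. Genes entered the test when FPKM was at least 0.5 in at least 15 of the 30 single-heart libraries, which left 9461 genes. Differences were tested with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3 on log2(scaled FPKM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is therefore on the log2(FPKM + 1) scale and understates the change of low genes. Gene lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Transcript usage was tested with diffSplice and Simes p-values over transcripts with mean scaled FPKM of at least 0.5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

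The 36 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Of 881 list entries, 828 were matched to the table, 40 of them through a transcript identifier. The rule named the 12 genes with the largest positive and the 12 with the largest negative change among those past the threshold, NPPA, NPPB, MYH6, MYH7, ATP2A2, SERPINA3 and IL1RL1 whatever their result, up to 4 members of each list with the smallest p, and the 10 genes with the smallest p for transcript usage. Of the 127 genes the rule names, the report prints 48 and genes of the usage test; which to print was decided after the values were seen. Other genes named were chosen after their values were seen, and are said to be. A p or count adjusted over the list alone is not adjusted across the 36 lists. Levels are means ± SD of scaled FPKM over 15 hearts per group, and log2 fold changes are ICM over control ± standard error.

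Depth was read from the low values. For transcripts of known length, 59.8 to 66.6% of low values lay within 0.1 of a whole number of fragment steps, where 20% would by chance. The steps implied 6890000 to 13700000 fragments per single-heart library. The pools implied 39700000 reads for control and 32700000 for ICM. Since many values were not whole, no count test was run. A group of 7 libraries (4 control, 3 ICM) implied 6890000 to 8050000 fragments, and the others (11 control, 12 ICM) at least 9630000. This depth class was found in the data and is used as a technical batch. The labels name no batch.

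The procedures were tested on simulated data made from the real libraries. Of 50 genes changed 1.5-fold among 9461, 38 (76%) were recovered, and all 50 were recovered at each of 2-, 3- and 4-fold, with 1 false call. All these changes were put in together, which makes the adjusted threshold easier to pass. They were added on the log2 scale, so low genes got the full fold. A count of 0 called genes in the real data therefore does not show that 2-fold changes were absent. For transcript usage, all 200 of 200 genes with a 3-fold change were recovered among 3437 by diffSplice, with 0 other genes. These simulations shuffled the residuals of whole libraries, so genes kept the variation they share, while the changed genes were drawn at random. Alternatives were a pseudocount of 0.1, no scaling, quantile normalization, no filter, a mean scaled FPKM of at least 5, library weights, a robust prior, the replicate number as a block, a residual component as covariate, and leaving out each library. Alternatives and tests added after seeing the data are named as such in the closing section.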

Results

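Gene expression was measured by ribosome-depleted RNA sequencing in the left ventricle of 15 control hearts and 15 ICM hearts, with 1 library per heart, and in 1 pooled library per group. The comparison asks which genes and transcripts differ between non-failing hearts and hearts failing after coronary disease. The single-heart libraries implied 6890000 to 13700000 fragments each. MTRNR2L2, a nuclear copy of mitochondrial ribosomal RNA sequence, was the most abundant transcript in 29 of 30 libraries. The most abundant transcript took 6.26 to 25.6% of FPKM, which is why libraries were scaled. Levels of genes with several transcripts are sums that may count shared fragments repeatedly. Spread is spread between hearts, and with 1 library per heart it holds donor and technical variation together.

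ICM hearts held more RNA of the natriuretic peptides and less of the calcium pump and of the fast myosin. NPPA (NM_006172), the atrial natriuretic peptide, stood at 158 ± 177 scaled FPKM in ICM and 50.9 ± 112 in control hearts (SD, n = 15 each), a log2 fold change of 2.70 ± 0.73, and 14 of 15 ICM hearts lay above the control median of 8.45. The control mean was 23.6 without control replicate 15, which held 433. NPPB (NM_002521), the B-type peptide, stood at 119.7 ± 102 and 70.9 ± 120.2, a log2 fold change of 2.13 ± 0.72, and its control mean was 44.1 without control replicate 12, which held 446. ATP2A2 (2 transcripts summed, NM_001681 the first), the pump that returns calcium to the sarcoplasmic reticulum, stood at 48.9 ± 9.51 and 76.7 ± 29.7, a log2 fold change of -0.56 ± 0.16, with 1 of 15 ICM hearts above the control median. MYH6 (NM_002471), the alpha myosin heavy chain, had a log2 fold change of -0.77 ± 0.25, and its close paralog MYH7, with which it can share fragments, -0.14 ± 0.29 (0.013 without scaling).

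SERPINA3, an acute-phase protease inhibitor, had a log2 fold change of -1.13 ± 0.42. IL1RL1, a receptor for interleukin 33, reached 0.5 FPKM in 10 libraries and was not tested; its levels were 0.810 ± 1.38 in ICM and 0.909 ± 0.897 in control hearts. Adjusted over the list alone, 5 of these 6 tested preset genes passed limma's test, with adjusted p = 0.00373 for NPPA and ATP2A2, 0.00826 for NPPB and MYH6, 0.0143 for SERPINA3 and 0.626 for MYH7. Over all 9461 genes, limma called 0 genes, and the smallest adjusted p was 0.218. At an unadjusted p under 0.05 there were 845 genes, 441 higher and 404 lower in ICM, where 473 would on average by chance. This excess does not exclude chance, since 19 of 100 splits of the libraries, the real one included, gave at least 845. Weighting the libraries called 22 genes, among them NPPA, LTBP2, ASPN, COL8A1, MFAP4, CD14 and PPP1R1A. Without scaling, 93.9% of the genes at that unadjusted level were higher in ICM, against 52.2% with scaling. Within the deeper libraries the log2 fold changes were 2.50 for NPPA, 2.32 for NPPB and -0.60 for ATP2A2, and within the shallower 3.15, 1.56 and -0.45; 0 genes were called in either, with 526 and 709 at an unadjusted p under 0.05.

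**Figure D1:**
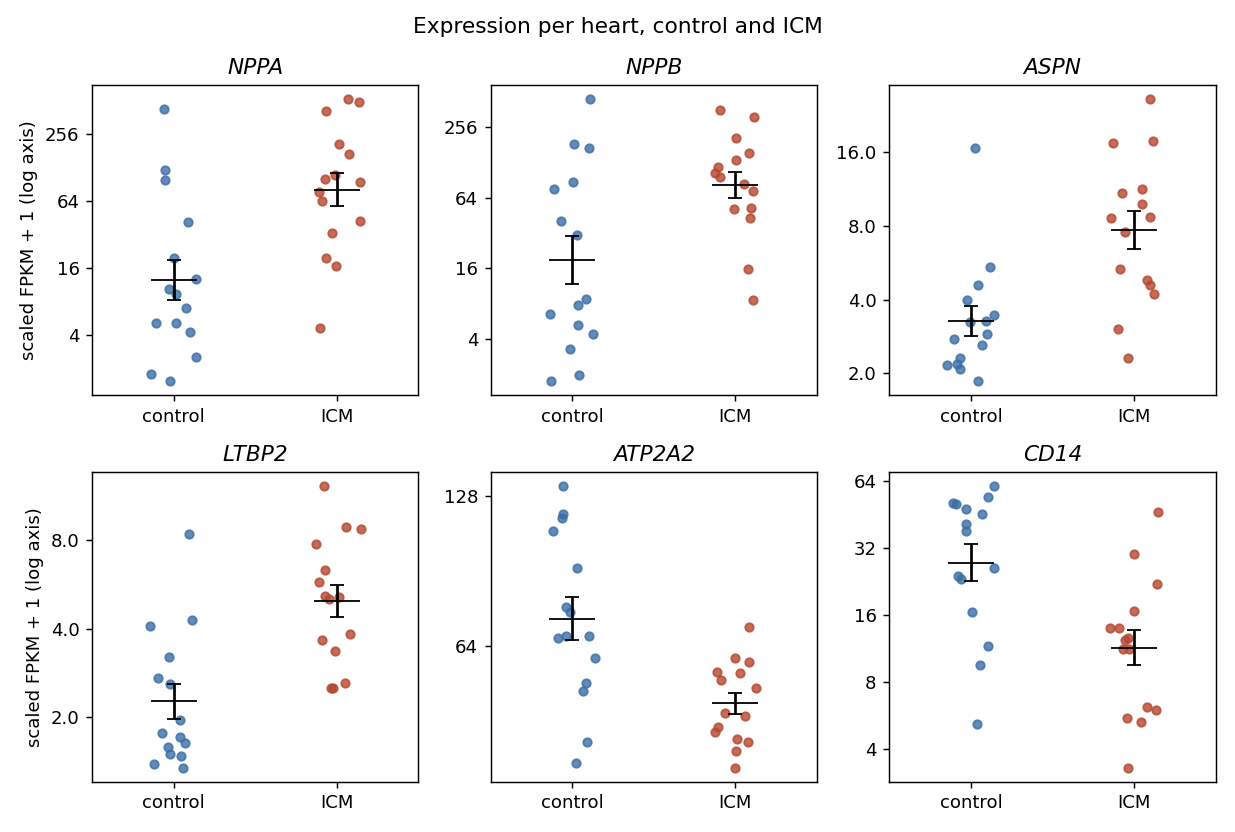
Scaled FPKM plus 1 on a log axis for 6 genes, with 1 point per heart (15 control, 15 ICM) and black bars for the mean and standard error on the log2 scale. NPPA ranged from 0.563 to 433 scaled FPKM in control and from 3.70 to 532 in ICM hearts, and ATP2A2 from 36.2 to 133 and from 35.4 to 68.9.

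Extracellular matrix and fibroblast genes had mostly positive fold changes, ICM over control. Of 42 tested members of the matrix and fibrosis list, 37 had positive fold changes, with a median log2 fold change of 0.45. LTBP2, which binds elastic fibres, went from 1.64 ± 1.87 to 4.57 ± 2.81 scaled FPKM (log2 fold change 1.14 ± 0.25), and all 15 ICM hearts lay above the control median. ASPN, a small leucine-rich proteoglycan, went from 2.98 ± 3.67 to 8.54 ± 6.63 (1.23 ± 0.31). COL8A1, a short-chain collagen, and MFAP4, a microfibril protein, had log2 fold changes of 0.83 ± 0.21 and 0.97 ± 0.25. Adjusted over the list alone 9 members rose and 0 fell, with adjusted p from 0.00353 for LTBP2, and over all genes 0 rose and 0 fell. This changed with 1 heart: without control replicate 15, limma called 8 genes over all genes, among them the members LTBP2, LUM, ASPN, FMOD, COL8A1 and MFAP4 (adjusted p = 0.0273 to 0.0464), of which FMOD was chosen after its values were seen. The other 29 such fits called at most 1 gene. The fibroblast marker list, which shares 9 tested members with it, had 20 of 23 members above 0 and a median of 0.32. POSTN, the matricellular protein periostin, had a log2 fold change of 1.44 ± 0.38, PI16 1.09 ± 0.29, LUM 1.06 ± 0.30 and OGN 0.82 ± 0.26; these 4 rose adjusted over the list alone, and 0 did over all genes.

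Camera with its preset correlation called both lists, with adjusted p = 7.8e-17 for matrix and 5.3e-08 for fibroblast markers. With an estimated correlation the adjusted p was 0.459 for both, and the unadjusted p 0.0306 and 0.0270. The mean of each heart's fibroblast marker values, relative to all its genes, differed by 0.45 ± 0.16 with 14 of 15 ICM hearts above the control median (two-sided permutation test, p = 0.00533, adjusted p = 0.0373 over 7 lists). The matrix mean differed by 0.52 ± 0.21 (p = 0.0175, adjusted p = 0.0612). Permuting hearts only within their depth class gave p = 0.0056 (adjusted 0.0392) for fibroblast markers and p = 0.0188 (adjusted 0.0658) for matrix. These permutation tests of 7 lists were chosen after the camera results were seen. Endothelial markers differed by -0.036 ± 0.053 (p = 0.510, adjusted p = 0.595) and pericyte and smooth muscle markers by 0.0080 ± 0.063 (p = 0.899, adjusted p = 0.899). The latter mean hides members of both directions, with 10 above and 9 below 0. At an unadjusted limma p under 0.05, 3 of these were higher and 2 lower in ICM. Within the deeper libraries the matrix mean stood 0.60 above all genes and within the shallower 0.26; for fibroblast markers these were 0.47 and 0.36.

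**Figure D2:**
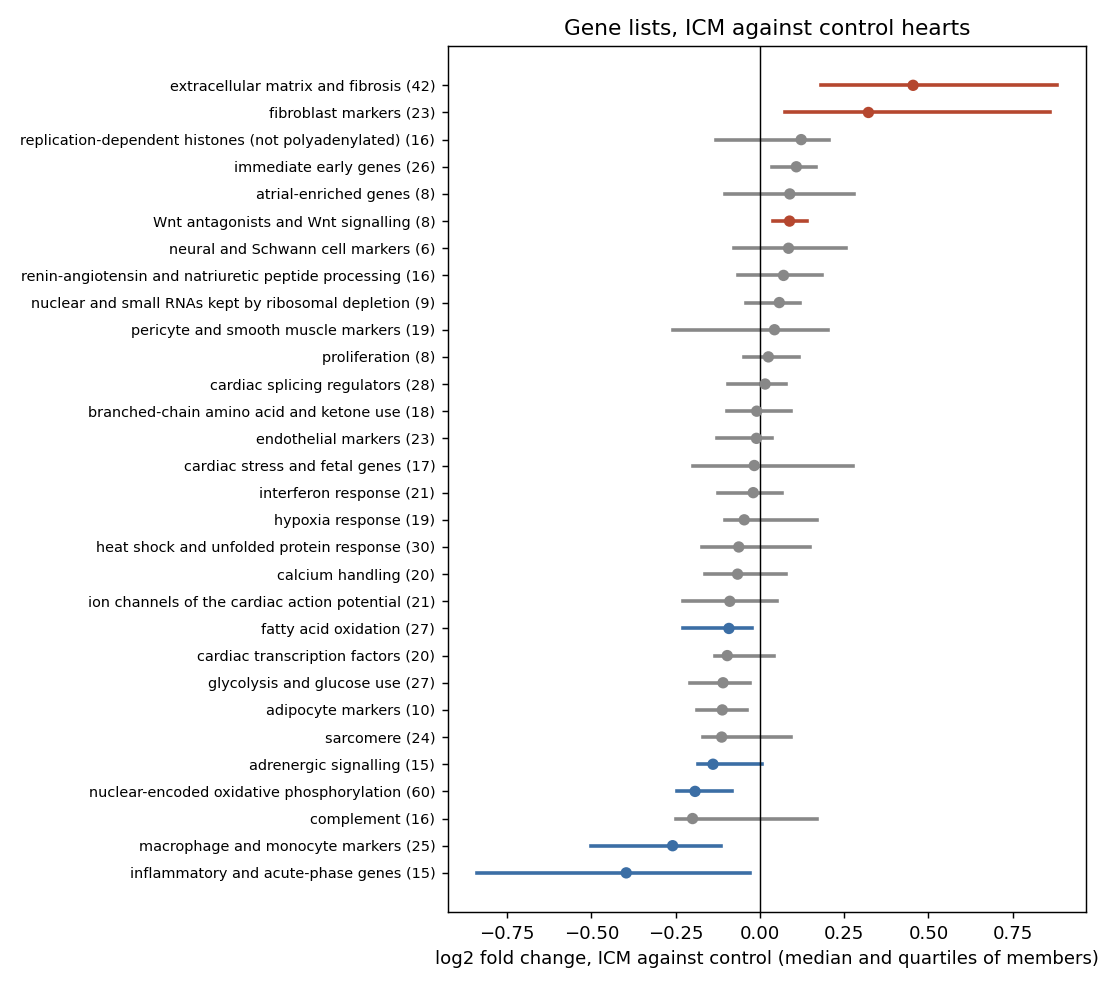
Median log2 fold change (points) and quartiles (lines) of the tested members of 30 gene lists, ICM against control, with the number of members in brackets. Red and blue lists passed camera with a preset correlation as higher or lower, grey lists did not; matrix and fibroblast lists have the highest medians, 0.45 and 0.32, and inflammatory genes the lowest, -0.40.

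Macrophage and inflammatory genes had mostly negative fold changes, but permuting the hearts did not separate the groups for either list. CD14, the monocyte co-receptor for endotoxin, went from 32.7 ± 18.1 scaled FPKM in control to 13.5 ± 11.2 in ICM hearts (log2 fold change -1.27 ± 0.36), and 1 of 15 ICM hearts lay above the control median. It was the 1 member of 25 macrophage markers that fell adjusted over the list alone (adjusted p = 0.0288); over all genes 0 did. The lectin CD209 had a log2 fold change of -0.73 ± 0.26, F13A1 -0.59 ± 0.27 and HMOX1 -0.37 ± 0.16, and 22 of the 25 members lay below 0. Of 15 inflammatory and acute-phase genes 12 lay below 0, with a median of -0.40; STAT3 had -0.54 ± 0.18, SERPINA1 -0.89 ± 0.39 and S100A9 -0.89 ± 0.41, and 0 passed adjusted over the list alone or over all genes. Camera called both lists (adjusted p = 0.000199 and 0.00804), with adjusted p = 0.728 for both with an estimated correlation. Permuting the hearts gave p = 0.175 (adjusted 0.306) for the macrophage and p = 0.0764 (adjusted 0.178) for the inflammatory mean. Among 4 tested neutrophil genes, too few for a list test, S100A9, FPR1 (-0.68 ± 0.36), S100A8 (-0.41 ± 0.38) and CSF3R (0.06 ± 0.21) did not pass adjusted over the list alone or over all genes.

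Oxidative phosphorylation and fatty acid oxidation genes had mostly negative fold changes, and only camera with its preset correlation called them. Of 60 nuclear-encoded oxidative phosphorylation genes 57 lay below 0, with a median of -0.19; NDUFB9 of complex I had -0.37 ± 0.17 and CYC1 of complex III -0.32 ± 0.18. Fatty acid oxidation had a median of -0.09 with 21 of 27 members below 0; HADHA and HADHB, the subunits of the trifunctional protein, had -0.33 ± 0.13 and -0.38 ± 0.14, and ACADVL -0.33 ± 0.15 with 0 of 15 ICM hearts above the control median. In both lists 0 members passed adjusted over the list alone or over all genes. Camera called both (adjusted p = 9.89e-06 and 0.0345), and both had adjusted p = 0.728 with an estimated correlation. Permuting the hearts gave p = 0.238 (adjusted 0.333) for oxidative phosphorylation. The fatty acid oxidation mean against all genes was -0.15 within the deeper libraries and 0.084 within the shallower, and its call held in 18 of 30 fits that left out 1 library. Over the other alternatives its call held in 9 of 16. Among those that lost it were no scaling, quantile normalization, library weights and the depth class as a term (camera adjusted p = 0.0992, 0.0936, 0.123 and 0.0530). Glycolysis genes had a median of -0.11 (camera adjusted p = 0.0931) and branched-chain amino acid and ketone genes -0.0094 (0.888).

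Adrenergic signalling genes had a median log2 fold change of -0.14, with 11 of 15 below 0. PPP1R1A, an inhibitor of protein phosphatase 1, went from 3.93 ± 2.28 to 1.77 ± 0.925 scaled FPKM (log2 fold change -0.75 ± 0.19) and was the 1 member that fell adjusted over the list alone (adjusted p = 0.00733). The receptor kinase GRK5 had -0.24 ± 0.09. The 8 tested Wnt genes all lay above 0 with a median of 0.09; the receptor FZD1 had 0.27 ± 0.11 and 0 passed adjusted over the list alone. Over all genes 0 members of either list passed. Camera called both lists (adjusted p = 0.0345 and 0.0479); with an estimated correlation adjusted p = 0.675 for both. Within the deeper libraries neither was called (adjusted p = 0.0867 and 0.0543), nor within the shallower (0.0811 and 0.652), and over fits that left out 1 library the calls held in 21 and 8 of 30. Over the other alternatives the calls held in 8 of 16 and 7 of 15. Both were lost with no scaling (camera adjusted p = 0.0582 for both), quantile normalization (0.103 and 0.0614) and the depth class as a term (0.0582 for both).

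Contractile and electrical genes had fold changes in both directions, and none of their lists was called in the reported fit. In the cardiac stress and fetal list NPPA and NPPB rose adjusted over the list alone (adjusted p = 0.0140 and 0.0468), while the list's median was -0.02, its mean 0.27 and its camera direction upward (adjusted p = 0.284). Among 20 calcium handling genes PPP1R1A and ATP2A2 fell adjusted over the list alone (adjusted p = 0.00978 and 0.0124) and the median was -0.07 (0.285). KCNIP2, a subunit of the transient outward potassium channel, went from 46.8 ± 46.4 to 11.5 ± 9.19 scaled FPKM (log2 fold change -1.48 ± 0.47), and the pore gene KCND3 had -0.31 ± 0.11; adjusted over the list of ion channels alone p = 0.0660 for both, and the list's median was -0.09 (0.285). LMOD2, which sets thin filament length, had 0.81 ± 0.29, and the sarcomere median was -0.11 (0.405). NKX2-5 and TBX20 had -0.58 ± 0.22 and -0.29 ± 0.14 among cardiac transcription factors (median -0.10, 0.284). Atrial-enriched genes had a median of 0.09 (0.284), with NPPA the 1 member past the threshold adjusted over the list alone (adjusted p = 0.00659). Over all genes 0 members of these lists passed.

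Of the remaining lists, camera called none. The medians and camera adjusted p were 0.11 and 0.114 for immediate early genes, 0.12 and 0.298 for replication-dependent histones, 0.07 and 0.331 for renin-angiotensin and natriuretic processing, 0.08 and 0.405 for neural markers, -0.20 and 0.405 for complement, 0.03 and 0.475 for proliferation, 0.02 and 0.678 for splicing regulators. They were -0.06 and 0.786 for heat shock, 0.06 and 0.813 for nuclear and small RNAs, -0.02 and 0.888 for interferon response, -0.11 and 0.284 for adipocyte markers, -0.01 and 0.472 for endothelial markers, 0.04 and 0.679 for pericyte and smooth muscle markers. The hypoxia list had a median of -0.05 and a mean of 0.03 with camera's direction upward (0.297); the mitophagy receptor BNIP3L rose adjusted over the list alone (0.23 ± 0.07, adjusted p = 0.0297). Adjusted over the list alone, the glycerol phosphate enzyme GPD1 of the adipocyte list fell (-0.52 ± 0.17, adjusted p = 0.0386) and HIST1H2AE rose (0.48 ± 0.14, adjusted p = 0.0212). SCN7A and MBP of the neural list had 0.30 ± 0.15 and 0.41 ± 0.17; these did not pass adjusted over the list alone, and over all genes 0 members of these lists passed.

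The red blood cell list had 4 tested genes, all globins, too few for a list test. HBB, the beta globin, went from 27.0 ± 36.6 to 48.4 ± 45.8 scaled FPKM (log2 fold change 1.47 ± 0.51), and HBD, HBA1 and HBA2 had 0.81 ± 0.31, 1.06 ± 0.43 and 0.84 ± 0.38. All 4 tested globin genes rose adjusted over the list alone (adjusted p = 0.0255 for HBB, HBD and HBA1, 0.0360 for HBA2), and over all genes 0 did. HBA1 and HBA2 are near-identical copies and cannot be told apart here. HBD stood at 0 in both pools, which hold RNA of the same hearts, so its rise was not seen there. HBB, HBA1 and HBA2 were higher in the ICM pool, with log2 ratios of 1.99, 0.81 and 0.71. T and NK cell markers and B cell markers had 1 tested member each, CD4 (-0.000062 ± 0.23) and CD79B (0.17 ± 0.20). Mast cell markers and mitochondrially encoded messages had 0 tested members.

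Transcript usage was not found to differ. Limma's diffSplice called 0 of 3437 genes with several transcripts, with 0 genes at an unadjusted p under 0.05 and a smallest Simes p of 0.118 for DEF8. The next were CLCN6 (0.166), ABCC5 (0.233), ATP1A1OS (0.255), LARP6 (0.261), WHSC1L1 (0.270), DLC1 (0.277), ZNF655 (0.295), MBP (0.319) and BCL2 (0.329). A limma test of each transcript relative to its gene mean, added after seeing the data, called 0 of 10269 transcripts, with 563 at an unadjusted p under 0.05. Since the deposited transcripts of a gene moved together with a median correlation of 0.9986 over 1363 genes, the table may hold little information on usage. With 0 of 3437 genes at an unadjusted p under 0.05, diffSplice also gave fewer small p-values than chance alone would. It was thus too strict here, and its 0 calls decide little. The test relative to the gene mean did give small p-values, and it called 0 after adjustment. A count of 0 does not show that usage was equal. The simulated changes were put into the transcript values themselves, so their recovery does not answer this.

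The pooled libraries, 1 per group, have no replicate check. NPPA stood at 178 scaled FPKM in the ICM pool and 27.4 in the control pool, ASPN at 44.0 and 8.19, CD14 at 11.5 and 43.0, and SERPINA3 at 2.15 and 19.8. NPPB stood at 151 and 140.0, against single-heart means of 119.7 and 70.9. A pool mixes RNA amounts, so 1 very high heart weighs more there than in a mean of log2 values. The log2 values of pools and single hearts are therefore unlike measures. Across the 9461 genes, which are not independent replicates, the pool log2 ratio and the single-heart log2 fold change had a Spearman correlation of 0.517, and 6435 (68.0%) had the same direction. Among the 845 genes at an unadjusted p under 0.05, which were selected in the same hearts, the correlation was 0.838 and 752 (89.0%) had the same direction. The pools hold RNA of the same hearts, so this checks the sequencing and not the donors. The matrix and fibroblast lists had pool medians of 0.71 and 0.85, both at percentile 100 of 10000 random lists matched on expression, and macrophage markers -0.71 at percentile 0. Genes of a random list need not vary together as members of these lists do. With 1 pool per group, the percentiles are thus ranks and do not test for chance. Inflammatory genes had -0.42 at percentile 0.09, against -0.40 in single hearts, and adrenergic signalling -0.14 at percentile 24.955, against -0.14. Some lists differed from the single hearts, and how far the unlike measure accounts for this was not tested. Interferon genes had a pool median of 0.42 at percentile 100, against -0.02 in single hearts, and oxidative phosphorylation -0.02 at percentile 90.5, against -0.19. Cardiac stress genes had -0.44 at percentile 0.145, against camera's upward direction, and heat shock -0.35 at percentile 0.03, against -0.06.

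In the authors' deposited table, 1035 transcripts of 623 genes had an adjusted p under 0.05, 746 higher and 289 lower in ICM. Of these, 1016 had the same direction in limma on the same transcripts and 499 an unadjusted limma p under 0.05, while 0 transcripts passed limma with adjustment. That limma fit ran on log2(scaled FPKM + 1) of all 27825 transcripts without a filter. The pseudocount shrinks the fold change of low transcripts, and the authors' model is another one. The 2 results are thus not like for like, and the cause of the gap was not tested. For the authors' called transcripts, the single highest library of the higher group held a median of 26.1% of that group's FPKM, against 14.1% for the 20 uncalled transcripts nearest in mean level to each and 6.67% if all 15 libraries were equal. For the 364 called transcripts with mean scaled FPKM of at least 0.5 these medians were 22.2 and 10.8%. The comparison at like level was chosen after the values were seen. Over all 1035 called transcripts, 175 (16.9%) had over 50% of that group's FPKM in 1 library. Of the 100 transcripts with the smallest adjusted p in the authors' deposited table, 70 did. Leaving out the highest library of the higher group for each transcript turned the direction of 95 of the 1035. A mean scaled FPKM under 0.5 was found for 671 of them.

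Chosen after the values were seen, 16 genes had 1 library at least 10 times above the next and at least 5 scaled FPKM. In ICM replicate 4 these included CXCL10, CXCL9 and CXCL11, interferon-induced chemokines, and IDO1, ICAM1, GBP1 and IRF1. CXCL10 reached 125 scaled FPKM there, against at most 0.438 in any other heart, and stood at 48.2 in the ICM pool and 0.536 in the control pool. In ICM replicate 5, COL1A1 reached 105.5 and the pools held 5.31 and 0.722. ANP32E reached 208 in control replicate 11, while the control pool held 3.63 and the ICM pool 3.79. All 16 had an adjusted p under 0.05 in the authors' deposited table.

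**Figure D3:**
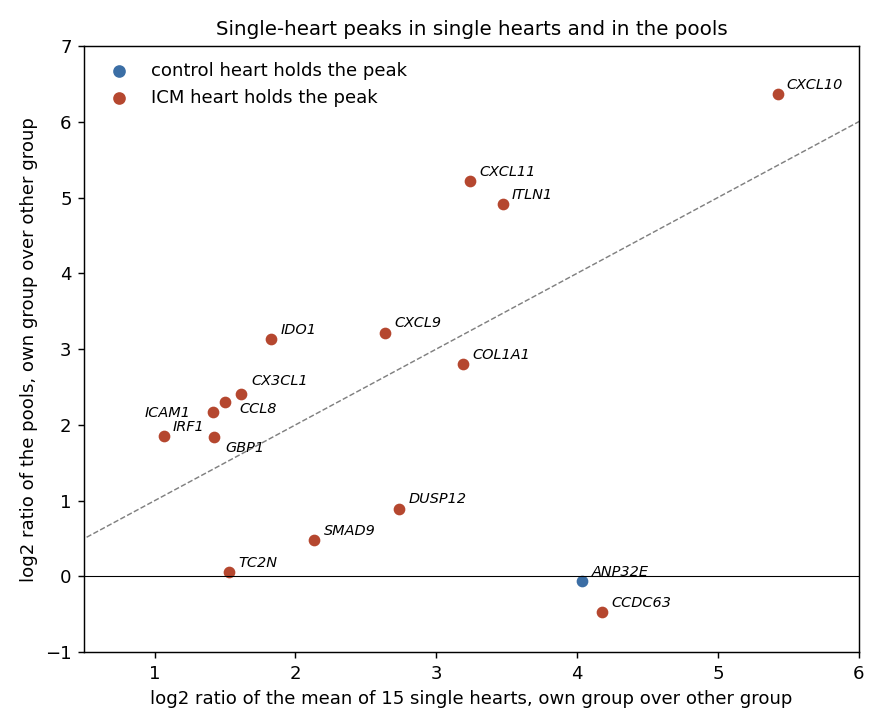
Log2 ratio of the pools (vertical) against the log2 ratio of the group means of single hearts (horizontal), own group over other group, for 16 genes with a single-heart peak; the dashed line marks equal values. CXCL10 lies highest at 6.36 in the pools, and ANP32E at -0.06 although its single-heart ratio is 4.04.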

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

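All alternatives were fixed before the data were examined except the highest transcript per gene, the depth class term and subsets, leaving out 4 libraries that stand apart (control replicates 8 and 12, ICM replicates 5 and 14), and the test relative to the gene mean. The count of genes past the threshold was 0 as reported and 22 with library weights (15 higher, 7 lower), of which 5 changed at least 2-fold; the other settings, the depth subsets and the fit without those 4 libraries gave 0 for both. Leaving out single libraries gave 0 to 8 genes and 0 to 5 at least 2-fold: 1 gene without control replicate 13, 8 without control replicate 15, otherwise 0, with 704 to 1130 at an unadjusted p under 0.05. Called lists numbered 8 as reported, 5 with no scaling, 5 with quantile normalization, 5 with the depth class as a term, 14 with no filter, 0 with camera's estimated correlation, 0 with fry, and 5 to 12 without single libraries (5 without control replicates 3, 4 or 9 or ICM replicate 5). Transcript usage gave 0 in the settings run. The cause of these shifts was not tested, except that an estimated correlation allows by construction for members that vary together. The replicate block gave 0 genes, 0 at least 2-fold, 8 lists and 0 genes for usage. Of 15 same-numbered pairs 7 correlated above 0.1, and 3 of 30 libraries correlated best with their own number, so the numbers were not taken as pairs. Depth limits low genes, for which the pseudocount of 1 shrinks a fold change.

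Matrix, fibroblast, oxidative phosphorylation, macrophage and inflammatory lists kept their call in all 30 leave-outs. Fatty acid oxidation lost it without control replicates 3, 4, 6, 7, 9, 10, 11, 13 or 14 or ICM replicates 5, 8 or 14 (adjusted p 0.000411 to 0.422 over the 30), and adrenergic signalling without control replicates 3, 4, 9, 10 or 13 or ICM replicates 5, 13, 14 or 15 (0.00865 to 0.195). The Wnt list kept it without control replicates 6, 8, 10 or 13 or ICM replicates 2, 10, 13 or 14 and lost it otherwise (0.0262 to 0.168). Immediate early genes gained a call without control replicates 5, 8, 12 or 15 or ICM replicates 7 or 10, glycolysis without control replicates 8 or 12 or ICM replicates 1 or 9, and cardiac transcription factors, ion channels and sarcomere without control replicate 12. The cardiac stress list gained one with library weights and without the 4 libraries. Of 650 values of the 48 rule-named genes printed in the report, 637 kept direction and side in the other settings, and of 473 list values 408. All 127 genes of the rule were run first, and the values below were limited to the 48 after that outcome was seen. Over the 127, 1686 of 1707 values kept direction and side and 14 turned. The 8 turned values not printed below are those of AQP7, NR2F2, CFD, PYGM, KDM3A, PPP1R15A, IFITM1 and MCAM, all in the shallower libraries alone.

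The direction turned in 6 gene values and 25 list values, each with the mean log2 difference given here (for lists, against all genes, the direction being that of camera's ranking), and the cause was not tested. With no scaling, branched-chain amino acid and ketone use gave -0.0068, MYH7 0.013 and CD4 0.12. With quantile normalization heat shock gave -0.023 and CD4 0.039. With no filter interferon response gave 0.037 and neural markers 0.027. With the stricter filter branched-chain use gave 0.038 and nuclear RNAs -0.040. Library weights gave 0.017 for branched-chain use and -0.0051 for CSF3R. A residual component as covariate gave -0.022 for branched-chain use. The highest transcript per gene gave 0.022 for branched-chain use and -0.021 for nuclear RNAs. The deeper libraries alone gave 0.0075 for branched-chain use, 0.0089 for nuclear RNAs and -0.089 for CD79B. The shallower libraries alone (4 control, 3 ICM) gave 0.057 for adipocyte markers, 0.17 for atrial genes, -0.018 for branched-chain use, 0.053 for cardiac stress, 0.020 for complement, 0.084 for fatty acid oxidation, 0.016 for glycolysis, -0.021 for heat shock, -0.12 for pericyte markers, -0.083 for histones, 0.098 for sarcomere and 0.13 for MYH7. Leaving out the 4 libraries gave 0.0048 for branched-chain use and 0.016 for sarcomere. Without single libraries the ranges that crossed 0, or turned camera's direction, were -0.13 to 0.11 for CD4, -0.030 to 0.20 for CSF3R, -0.078 to 0.040 for branched-chain use, -0.12 to 0.0057 for heat shock, -0.071 to 0.091 for interferon, 0.023 to 0.073 for nuclear RNAs and -0.13 to 0.041 for sarcomere; the library behind each end was not examined further.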

Other observations

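The relations across hearts and the splits for lists and unadjusted counts were specified before their own results were seen, but after the main fit, which guided the choice of lists. The splits for counts of 0, the grouping of splits by depth class, the tests of cell share, depth and single hearts, and the comparison of single-heart peaks with the pools were chosen after the values were seen.

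Across the 15 control hearts, a heart with more macrophage marker RNA also had more inflammatory and acute-phase RNA, with Pearson's r of 0.907 (permutation p = 1e-05, the smallest that 100000 permutations can give) and Spearman's rho of 0.843 (permutation p = 0.00012). The lists share 0 tested genes, and r was 0.852 without the 2 hearts farthest from the median. In the 15 ICM hearts r was 0.582 (permutation p = 0.0222), rho 0.575 (permutation p = 0.0270) and r 0.319 without the 2 farthest hearts, so the size of r there depends on those hearts. Matrix and oxidative phosphorylation lists went in opposite directions, with r = -0.757 in control (permutation p = 0.00198, rho -0.729 with permutation p = 0.00281) and -0.744 in ICM hearts (permutation p = 0.00402, rho -0.654 with permutation p = 0.0104). Without the 2 farthest hearts r was -0.650 and -0.295. The ICM relation meets the prediction written for it (r below -0.5 with p under 0.05), but the size of its r depends on 2 hearts. Leaving out the farthest hearts also narrows the range, which by itself weakens r, and leaving out other hearts was not compared. Adjusted over these 4 relations, p for r was 4e-05, 0.0222, 0.00396 and 0.00536 in the order given, and for rho at most 0.0270. Within the deeper libraries r was 0.924, 0.555, -0.786 and -0.779, and the shallower class held too few hearts. A shared state of macrophages and acute-phase genes across control hearts is one possible reading of r = 0.907, and no test separated it from other causes.

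Among 100 splits of the 30 libraries into groups of 15, the real one included, 100 gave at least the 0 genes and 0 genes changed 2-fold that the real groups gave, as any split must, so this says nothing about chance; other splits gave up to 14 and 12. For transcript usage all 100 gave 0, which likewise says nothing. At least the 8 real list calls came from 53 of the 100 splits, up to 19, so chance cannot be excluded for the count of called lists, which points to genes that vary together across hearts. An unadjusted count of at least 845 came from 19 splits, up to 1693, and chance cannot be excluded there either. The matrix list's mean shift of 0.52 was reached by 3 of the 100 splits, under the 5 set beforehand for chance, with 0.66 the highest of the others. The 2 others put 6 and 5 of the 7 shallower libraries on one side, and among the 57 splits that part these libraries as the real groups do, 1 reached it, the real one, with 0.50 the highest other. That is not adjusted for the 3 lists split here, which were chosen after the fit, nor for this list having the largest mean of 30. The permutation test of its heart means gave p = 0.0175, adjusted 0.0612 over 7 lists, so the evidence against chance is limited. The sizes of the shifts in oxidative phosphorylation (0.16) and macrophage markers (0.31) were reached by 26 and 23 splits, with highest others of 0.31 and 0.48, and chance cannot be excluded for them.

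Matrix and fibroblast genes had mostly positive fold changes, ICM over control. A lower share of cardiomyocytes, with the other cell types in unchanged proportions, would raise the markers of all these types alike. The tables argue against that form as the whole cause. Fibroblast markers moved 0.77 ± 0.25 above macrophage markers (log2, permutation p = 0.0059, adjusted p = 0.00907 over 4 contrasts). They moved 0.49 ± 0.16 above endothelial and 0.45 ± 0.16 above smooth muscle markers, whose mean averages members that went both ways. These contrasts were chosen after the list results were seen, and their p-values do not allow for that choice. A loss of cardiomyocytes filled by fibroblasts alone is also a lower share, and the contrasts cannot exclude it. The contrast without fibroblasts, endothelial above macrophage markers, was 0.28 ± 0.23 (permutation p = 0.231, adjusted p = 0.231). Permuting within the depth class gave p = 0.00542 for fibroblast against macrophage markers and 0.218 for endothelial against macrophage markers. Depth is argued against by the direction within each depth class, with a matrix mean 0.60 above all genes in the deeper libraries and 0.26 in the shallower. The prediction used camera's adjusted p in the deeper libraries, 1.06e-19, which is not calibrated here, since the preset correlation gave at least 8 list calls in 53 of 100 splits. A single heart with very high collagen is argued against by a mean shift of 0.42 without ICM replicate 5. More fibroblasts, or more matrix RNA per fibroblast, in failing hearts stays open as an untested biological hypothesis, and counting fibroblast nuclei in the same pieces would tell these 2 apart.

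Of the 16 single-heart peaks, 11 were at least 2-fold higher in the pool of their own group, which argues against an error in 1 library as the cause of them all. For COL1A1 the other hearts alone would give 1.41 (log2), so its 2.80 in the pools does not count here, and 10 peaks do; 9 of these are among the 11 peaks of ICM replicate 4, where an interferon response in that heart's tissue is a possible explanation for the 9. The other 2 peaks of that library, CCDC63 and TC2N, were not seen in the pool. The other 5 (ANP32E, CCDC63, TC2N, DUSP12 and SMAD9) were less than 2-fold higher although the single hearts gave more, which argues against RNA present in that heart as the cause of all peaks. An error in those libraries or in their processing stays open for these 5, as does a difference between the Illumina and SOLiD methods, which was not tested.

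On the first component of all genes, which held 22.5% of the variance, control replicates 8 and 12 and ICM replicates 5 and 14 lay at -40.0, -52.2, -30.1 and -43.8, and the other 26 libraries between -15.1 and 16.8. These 4 libraries also had the lowest library weights, 0.427, 0.376, 0.349 and 0.370. Genes chosen after their values were seen stood apart there: CPT1B, the mitochondrial entry enzyme for fatty acids, stood at 84.3, 32.5, 52.8 and 51.9 scaled FPKM against 130.3 to 254.9 in the other 26, and FBXO40, a muscle ubiquitin ligase subunit, at 0.922, 0.322, 3.36 and 0.425 against 3.57 to 13.2. NPPB stood at 183, 446, 50.9 and 313 against a median of 46.2 and up to 357 in the others, so it did not stand apart as these 2 did. Of genes chosen likewise, LDB3 stood at 88.1, 34.8, 61.9 and 119 against 158 to 441. XIRP2 stood at 733, 471, 22.3 and 447 against 21.7 to 295. For XIRP2, ICM replicate 5 thus lay within the range of the others, so the 4 libraries were not alike. The values are in the order of the libraries above. No explanation of this axis was tested. On component 4, control replicates 1 to 7 and ICM replicates 1 to 5 all had negative values, deeper libraries among them. ICM replicates 6 to 15 all had positive values, and control replicates 8 to 15 had both signs. The depth class therefore need not hold all grouping by library number, which was not tested.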
